A study of Homo sapiens with 12 samples.

How the data were processed

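RNA was sequenced from the human cell line RS4;11, a B-cell precursor acute lymphoblastic leukaemia line that carries the MLL-AF4 fusion. The labels list 12 libraries in 6 groups of 2 libraries: control, bortezomib at 20 nM, M3258 at 1 µM and at 50 nM, and ONX-0914 at 800 nM and at 50 nM. Bortezomib is a general proteasome inhibitor, and M3258 and ONX-0914 are described as immunoproteasome inhibitors. The length of treatment is not given in the sources used here. Per the labels, libraries were made with a poly-A selecting kit that does not mark strand and read as 150 bp pairs. The series text speaks of total RNA sequencing, which differs from the poly-A kit in the labels. Reads from a gene and from an overlapping gene on the other strand cannot be told apart in such libraries.

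The authors deposited a table of their own 5 comparisons, each treatment against control, over 12725 genes, and values per library were not analysed here. Per the submitters' processing notes, the tools and build named were Partek and hg38. The aligner, the counting step, the annotation and the statistical model are not given in the sources used here. Per the file headers, the deposited columns for each comparison are a p-value, an adjusted p-value, a ratio and a signed fold change, with a least-squares mean per group. The adjusted p-value in the authors' deposited table equals a Benjamini-Hochberg adjustment over its genes, with a largest difference of 3.33e-16. The deposited ratio is the quotient of the deposited group means. The authors' deposited group means sum to between 998029 and 998488 per group, and were therefore read as CPM (library-size scaled counts); the unit is inferred from the values. The smallest mean over the 6 groups was 1.03 CPM, so genes with lower levels had been left out before deposit. A depth of 20 M reads per library is stated, but the depth reached by each library is unknown here. No interval for counting error was computed.

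The deposited comparisons were described and not tested again, as fixed in the design. A gene was called changed at a deposited adjusted p under 0.05, and log2 ratios were computed from the deposited ratios. The labels give 2 libraries per group and do not say that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

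Comparisons between treated groups were part of the design, but are not among the deposited ones, and a test for them was chosen after the file had been seen. For each gene, a deposited p-value and log2 ratio imply a standard error once the degrees of freedom are known. The implied standard errors of a gene's comparisons differed least at 12.75 degrees of freedom, with a median difference of 1.14% over 2022 pairs of comparisons of a gene, both with an absolute log2 ratio of 1 or more. A shared standard error per gene was then fitted by least squares, with a median of 0.19 on the log2 scale and quartiles of 0.15 and 0.25. Each 95% interval printed is the log2 ratio with this derived standard error, and each difference between treatments was tested with it and adjusted by Benjamini-Hochberg. The 21 genes whose implied standard errors disagreed were left uncalled in these differences, none of them among the 5952 genes called in any deposited comparison. The procedure was tested on a deposited-style table simulated with limma 3.58.1 in R 4.3.3, over 12725 genes of which 200 were changed. For the simulated treated against treated comparison, limma called 188 genes directly and the recovered standard error called 191, of which 188 were shared and 15 were unchanged genes. The degrees of freedom recovered from the simulated table were 17.25, against a median of 18.75 used by limma. Among 100 genes changed by 1 on the log2 scale 79% were recovered, and among 100 changed by 2 it was 97%. When each deposited comparison was predicted from the standard error of the other 4, the calls were 405 in place of 402 for bortezomib and 5610 in place of 5543 for M3258 at 1 µM.

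Before the data were examined, 27 gene lists were fixed for stress responses, proteasome subunits, cell identity, cell cycle, antigen presentation and cell types other than B-cell precursors. A list was tested where 4 or more members were measured, by the percentile of its median log2 ratio among 10000 random lists matched on mean expression in 20 bins, adjusted over the lists of a comparison. This p takes genes as independent. It was checked with limma's cameraPR at preset correlations of 0.01 and 0.05; a correlation estimated from the data needs values per library and was not run. The marker list for erythroid and megakaryocyte cells had 1 measured member, GP9, and was not tested. The constitutive proteasome list also holds subunits and assembly chaperones that are not particular to that form of the proteasome. Except for some genes picked after their values were seen, genes named in the text followed a rule fixed before the data were examined. The rule takes PSMB5, PSMB8, PSMB9 and PSMB10, which are catalytic subunits but not all of those of the constitutive proteasome. It also takes the 5 largest rises and 5 largest falls among called genes with the higher group mean at 5 CPM or more. Lastly, it takes the 2 members with the smallest p of up to 8 called lists. The rule also gave a floor of 1 for other normalized units, and the 5 CPM floor was used because the unit was read as CPM. For differences between treatments the rule takes 3 rises, 3 falls and the genes already named against control. Clone names and pseudogenes are left out of the rises and falls.

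Gene positions and transcript lengths came from GENCODE release 29 on GRCh38, in which 12589 of the 12725 identifiers (98.9%) were found and 11365 of these were protein coding. Chance similarity between comparisons that share the 2 control libraries was simulated 100 times from unchanged groups. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Alternatives tried were an adjusted p threshold of 0.01, a change of 1 or more on the log2 scale, a floor of 5 CPM, recentring on the median, standard errors from the other comparisons, and 6 degrees of freedom. For correlations between comparisons, the alternatives were Spearman's and the genes called in either comparison.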

Results

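Gene expression was measured by RNA sequencing in RS4;11, a B-cell precursor acute lymphoblastic leukaemia line with the MLL-AF4 fusion. The 12 libraries formed 6 groups of 2: control, bortezomib at 20 nM, M3258 at 50 nM and 1 µM, and ONX-0914 at 50 nM and 800 nM. The series concerns proteotoxic stress and cell death after inhibition of the immunoproteasome, the form of the proteasome abundant in lymphoid cells. The authors' deposited table gives a mean in CPM per group, a ratio and a p-value for 12725 genes and each of the 5 treatments against control. It gives no value per library, so the depth reached by each library is unknown and no SD is given. The 95% intervals below come from the standard error derived from the deposited p-values.

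At an adjusted p under 0.05 in the authors' deposited table, bortezomib changed 402 genes, M3258 at 50 nM changed 1202 and M3258 at 1 µM changed 5543. ONX-0914 changed 1546 genes at 800 nM and a single gene, HSPA1A, at 50 nM. At 50 nM 297 of 12725 genes had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give. The same 101 genes were called higher, and 93 lower, with bortezomib, with both doses of M3258 and with ONX-0914 at 800 nM by the deposited adjusted p. Independent calls would share 0.042 and 0.27 genes, but these comparisons share the 2 control libraries, so the shared calls are not independent. Of these 101 genes, 24 belonged to the list of the cytosolic heat shock response, the chaperones induced by misfolded protein.

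**Figure D1:**
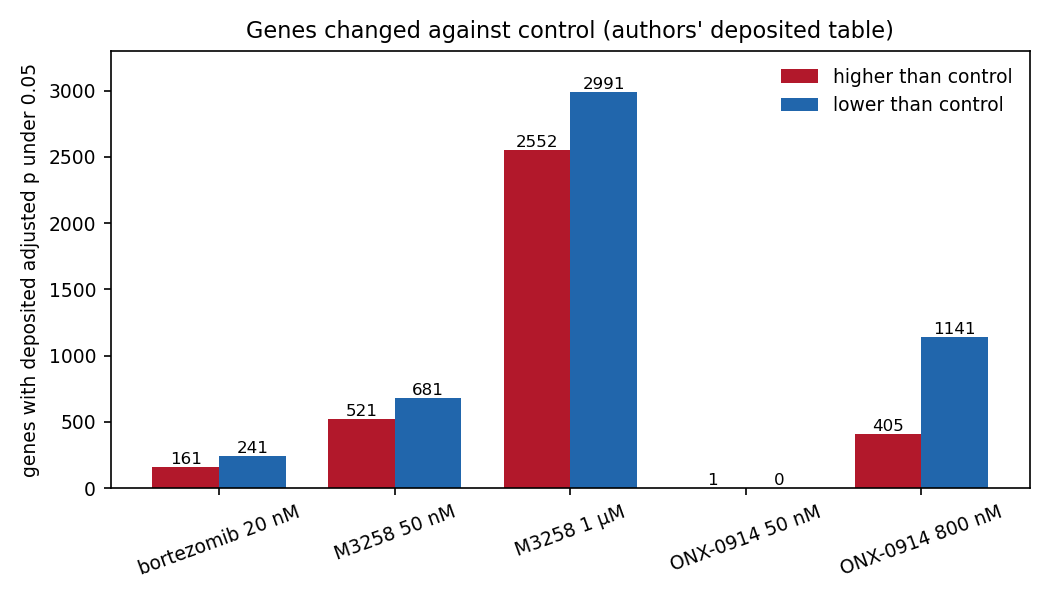
Bars give the number of genes with a deposited adjusted p under 0.05 for each treatment against control, with genes higher than control in red and lower in blue. M3258 at 1 µM had 2552 higher and 2991 lower genes, and ONX-0914 at 50 nM had 1 and 0.

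Bortezomib raised chaperone and stress genes. Of 28 measured heat shock genes, 24 rose and none fell by the adjusted p in the authors' deposited table (25 rose when adjusted over the list alone), with a median log2 ratio of 1.27. HSPA6, a strictly inducible HSP70, rose 99.6-fold in the authors' deposited table, from 0.539 to 53.7 CPM (log2 6.64, 95% interval 5.83 to 7.44). HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946 on GRCh38), the major inducible HSP70, rose 47.4-fold from 45.9 to 2176 CPM in the authors' deposited table (log2 5.57, interval 5.14 to 5.99). HSPA1B also rose, with a log2 ratio of 4.95, but its sequence is nearly identical to that of HSPA1A, so the split of reads between the pair is uncertain. Of 25 genes of the ATF4 integrated stress response, which adapts cells to unfolded protein and amino acid shortage, 12 rose and none fell by the deposited adjusted p (19 rose when adjusted over the list alone). CHAC1, a glutathione-degrading enzyme, rose 7.19-fold (log2 2.85, interval 2.47 to 3.22), and DDIT3, which encodes the transcription factor CHOP, rose 3.73-fold (log2 1.90, interval 1.56 to 2.23) in the authors' deposited table.

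Other lists higher with bortezomib included the proteasome, NRF2 and endoplasmic reticulum stress genes. The list of MYC and ribosome biogenesis genes was also higher than random lists (median 0.19, adjusted p = 0.013), with 0 of 23 genes called. By the authors' deposited table, 10 of 38 constitutive proteasome genes rose and none fell (25 rose when adjusted over the list alone), with a median log2 ratio of 0.42; PSMC2 had a ratio of 1.87 and PSMD7 one of 1.68. NRF2 targets, the oxidative stress genes, rose in 9 of 20 cases by the deposited adjusted p (11 when adjusted over the list alone), and among them OSGIN1 rose 11.7-fold and HMOX1, heme oxygenase, 11.6-fold. In the endoplasmic reticulum list 8 of 27 genes rose by the deposited adjusted p (13 when adjusted over the list alone), with HSPA5, the chaperone BiP, at a ratio of 2.42 and SDF2L1 at 1.99. Of the catalytic subunits, PSMB5 had a deposited ratio of 1.56 (log2 0.65, interval 0.25 to 1.04) that missed the threshold at an adjusted p of 0.092. The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 had deposited log2 ratios of -0.34, -0.11 and -0.31, with adjusted p of 0.29, 0.81 and 0.48.

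Mitotic and B-cell genes fell with bortezomib. In the authors' deposited table, 6 of 25 G2/M genes fell and none rose (18 fell when adjusted over the list alone), with KIF20A, a mitotic kinesin, at a ratio of 0.586 and CCNB1, cyclin B1, at 0.705. Of 20 B-cell precursor genes 5 fell and none rose by the deposited adjusted p (10 fell when adjusted over the list alone), with VPREB1, part of the surrogate light chain, at a ratio of 0.415 and CD22 at 0.585. Of 5 T-cell and NK-cell markers 1 fell (1 when adjusted over the list alone; median log2 -0.34, adjusted p = 0.068). The metallothioneins MT2A and MT1X, zinc-binding proteins whose gene family shares sequence, fell with deposited ratios of 0.437 and 0.573. The largest deposited falls among genes at 5 CPM or more in either group were those of TUBA1B-AS1 (log2 -4.10, interval -6.27 to -1.92), LCN8 (-2.71), F2RL3 (-1.99), TTC38 (-1.92) and C2orf81 (-1.86). TUBA1B-AS1 is an antisense gene, and its reads cannot be told from those of the opposite strand. The mitochondrially encoded list had a median log2 ratio of -0.28, with 0 of 13 genes called by the deposited adjusted p. At an adjusted p of 0.01 the number of genes called with bortezomib was 123 in place of 402. The calls for interferon-stimulated genes (median -0.39), mitochondrial transcripts, p53 targets (0.14) and myeloid markers (-0.35) were lost with cameraPR at a preset correlation of 0.05, where adjusted p was 0.10, 0.44, 0.43 and 0.34.

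**Figure D2:**
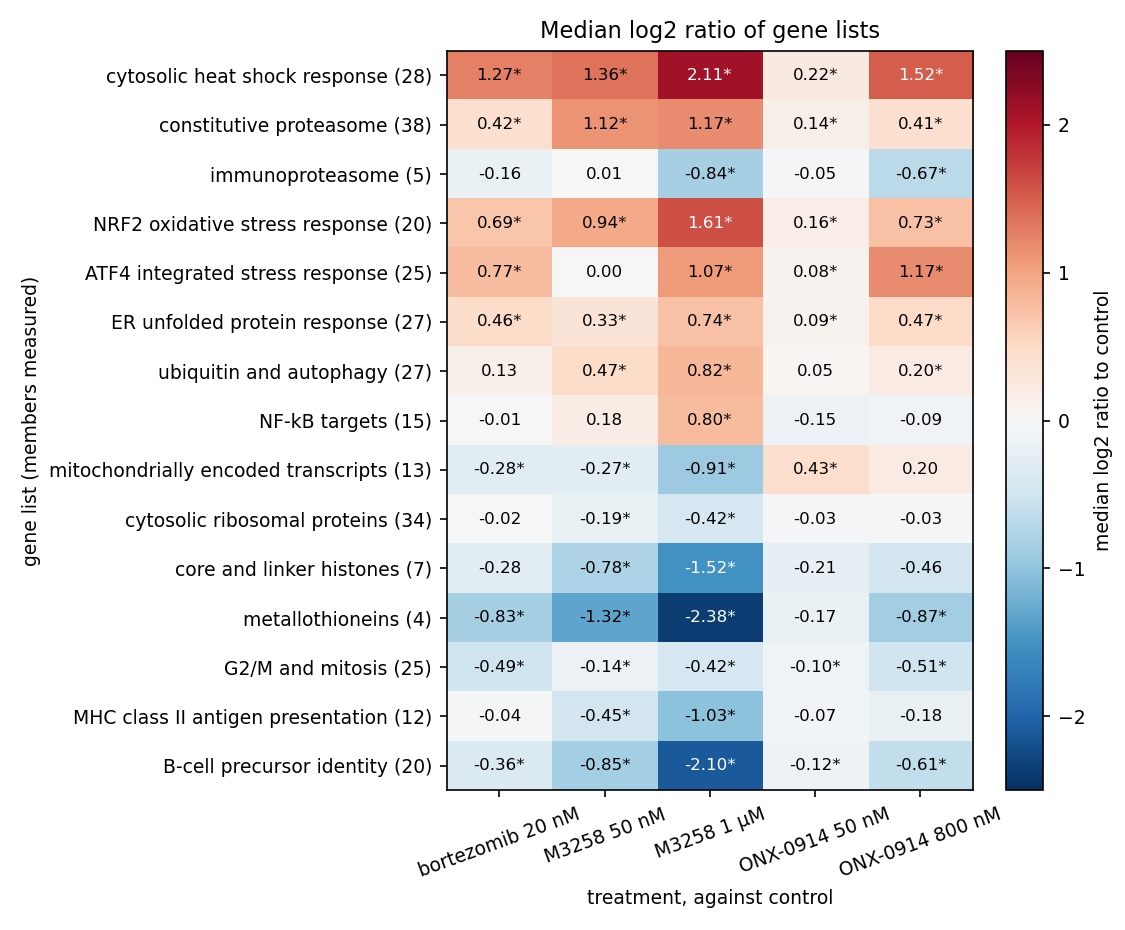
Each cell gives the median log2 ratio to control of a gene list (rows, with measured members in brackets) for a treatment (columns), and a star marks an adjusted p under 0.05 against random lists matched on expression. The heat shock list had medians of 1.27 with bortezomib and 2.11 with M3258 at 1 µM, and the B-cell list had -2.10 in the latter.

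M3258 at 50 nM raised heat shock and proteasome genes. In the authors' deposited table, 26 of 28 heat shock genes rose and none fell (27 rose when adjusted over the list alone; median log2 1.36), with HSPA1A 41.2-fold higher (log2 5.36, interval 4.94 to 5.79). Of 38 constitutive proteasome genes 33 rose and none fell by the deposited adjusted p (34 rose when adjusted over the list alone), with a median log2 ratio of 1.12. PSMB5, a constitutive catalytic subunit, rose 2.56-fold in the authors' deposited table (log2 1.35, interval 0.96 to 1.75). The ATPase subunit PSMC2 rose 2.97-fold and PSMC4 2.83-fold. PSMB8, PSMB9 and PSMB10 had deposited log2 ratios of -0.12, -0.05 and 0.05, with intervals of -0.47 to 0.23, -0.47 to 0.37 and -0.49 to 0.59. NRF2 targets rose in 15 of 20 cases by the deposited adjusted p (17 when adjusted over the list alone), with TALDO1, of the pentose phosphate pathway, at a ratio of 3.22 and SQSTM1, the autophagy receptor p62, at 3.77. In the ubiquitin and autophagy list 12 of 27 genes rose by the deposited adjusted p (15 when adjusted over the list alone), with the polyubiquitin gene UBC at a ratio of 3.11. In the endoplasmic reticulum list 10 of 27 rose by the deposited adjusted p (12 rose and 1 fell when adjusted over the list alone), with CALR at a ratio of 2.09 and CRELD2 at 1.91.

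The ATF4 list had a median log2 ratio of 0.003 with M3258 at 50 nM. In the authors' deposited table, 3 of its 25 genes rose, namely ATF3, PPP1R15A and SLC7A11, and CHAC1 fell (log2 -1.12), with the same numbers when adjusted over the list alone. These genes were named after their values were seen, and the list did not pass against random lists (adjusted p = 0.62). CXCL8, the neutrophil chemokine interleukin-8, had the largest rise among called genes at 5 CPM or more in either group, from a deposited 0.0622 CPM in control to 14.3 CPM (log2 7.84, interval 6.87 to 8.82); its fold is poorly defined because the control mean is so close to 0. PANX2 (log2 4.38), EGF (4.32) and HSPA6 (4.16) were the other large rises of the authors' deposited table. The largest deposited falls among such genes were those of LGR6 (-2.93, interval -3.23 to -2.63), ALDOC (-2.48), SAMD11 (-2.46) and CHI3L2 (-2.34), and PSD2 fell to a deposited ratio of 0.177. Of 20 B-cell precursor genes 14 fell and none rose by the deposited adjusted p (17 fell when adjusted over the list alone), with POU2AF1, a B-cell coactivator, at a ratio of 0.384 and CD72 at 0.389. The T-cell and NK-cell marker list was lower as well, with 4 of 5 genes fallen (5 when adjusted over the list alone; median log2 -0.75, adjusted p = 0.0035). Of 12 MHC class II genes 7 fell by the deposited adjusted p (7 when adjusted over the list alone), with CIITA, the class II transactivator, at a ratio of 0.584 and HLA-DMB at 0.461. MT1F and MT1X fell to deposited ratios of 0.326 and 0.464. The mitochondrially encoded list had a median of -0.27 with 0 of 13 genes called. At an adjusted p of 0.01 the count of changed genes was 541 in place of 1202. The calls for mitochondrial, ribosomal (median -0.19), cholesterol (-0.16), G2/M (-0.14) and pro-apoptotic (0.23) lists were lost with cameraPR at a correlation of 0.05, with adjusted p of 0.23, 0.21, 0.23, 0.32 and 0.43.

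M3258 at 1 µM gave the largest response of the 5 treatments by number of called genes. All 28 measured heat shock genes rose in the authors' deposited table (28 when adjusted over the list alone; median log2 2.11), with HSPA1A 122-fold higher, at 5612 CPM against 45.9 CPM (log2 6.93, interval 6.51 to 7.36), and HSPA6 148-fold higher. Of 38 constitutive proteasome genes 33 rose and 2 fell by the deposited adjusted p (33 and 2 when adjusted over the list alone), with PSMB5 2.70-fold (log2 1.43, interval 1.04 to 1.83), PSMC2 3.56-fold and PSMD14 3.35-fold higher. The 2 that fell, PSMG3 and PSMG4, named after their values were seen, encode assembly chaperones rather than subunits. By contrast 4 of 5 immunoproteasome genes fell in the authors' deposited table (4 when adjusted over the list alone): PSMB8 (log2 -1.17, interval -1.53 to -0.82), PSMB9 (-1.21, -1.63 to -0.79), PSMB10 (-0.84, -1.38 to -0.29) and PSME1. PSMB8 (ENSG00000204264, chromosome 6, 32840717 to 32844703, minus strand) overlaps the antisense gene PSMB8-AS1, which starts at 32844086 on the plus strand, and PSMB9 starts at 32844136, so reads of these genes can be shared. PSMB10 lies apart on chromosome 16, at 67934502 to 67937087.

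Of the stress lists, 24 of 25 ATF4 genes rose with M3258 at 1 µM by the deposited adjusted p (24 when adjusted over the list alone; median log2 1.07), with PPP1R15A at a ratio of 4.73 and ATF5 at 3.08. In the authors' deposited table, 18 of 20 NRF2 targets rose (18 rose and 2 fell when adjusted over the list alone), with SQSTM1 at a ratio of 5.31 and TALDO1 at 3.59. Of 27 ubiquitin and autophagy genes 19 rose (19 when adjusted over the list alone), with UBC at a deposited ratio of 5.77. In the endoplasmic reticulum list 16 of 27 rose and 2 fell by the deposited adjusted p (16 and 2 when adjusted over the list alone). The 2 that fell were SYVN1 and DERL3, named after their values were seen. NF-kB targets, inflammatory genes, rose in 9 and fell in 4 of 15 cases (10 and 4 when adjusted over the list alone), and CXCL8 reached 118.7 CPM in the authors' deposited table, against 0.0622 CPM in control. GABARAPL1, an autophagy gene, rose 43.9-fold by the authors' deposited table.

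B-cell precursor genes fell with M3258 at 1 µM in 16 of 20 cases by the deposited adjusted p, and none rose (16 fell when adjusted over the list alone; median log2 -2.10). VPREB3 fell to a deposited ratio of 0.0521, VPREB1 to 0.108 and CD22, a surface receptor of B cells, to 0.193. The T-cell and NK-cell marker list was lower as well, with 4 of 5 genes fallen (4 when adjusted over the list alone; median log2 -1.39, adjusted p = 0.0020 against random lists). Of 12 MHC class II genes 11 fell by the deposited adjusted p (11 when adjusted over the list alone), with CIITA at a ratio of 0.318 and HLA-DPA1 at 0.412; HLA genes share sequence, which makes their counts uncertain. In the authors' deposited table, 11 of 13 mitochondrially encoded transcripts fell (11 when adjusted over the list alone; median log2 -0.91), with MT-ND3 at 436 CPM against 908 CPM in control and MT-CO3 at 3230 against 6158 CPM. By the same table, 6 of 7 histone genes, 13 of 34 ribosomal protein genes, 13 of 25 G2/M genes and all 4 metallothioneins fell (6, 13, 13 and 4 when adjusted over the list alone). LGR6, a receptor of the Wnt pathway, fell from 222 to 7.25 CPM in the authors' deposited table (log2 -4.93, interval -5.23 to -4.64). GP1BB (log2 -5.75), the readthrough gene TMEM276-ZFTRAF1 (-5.35) and CHI3L2 (-4.91) were also among the largest deposited falls, with treated means under 0.3 CPM. At an adjusted p of 0.01 the count of changed genes was 3369 in place of 5543. The call for the cholesterol list (median -0.30) was lost with cameraPR, at an adjusted p of 0.25 with a correlation of 0.05.

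ONX-0914 at 800 nM raised 24 of 28 heat shock genes in the authors' deposited table (26 when adjusted over the list alone; median log2 1.52), with HSPA1A 63.0-fold (log2 5.98, interval 5.55 to 6.40) and HSPA6 124-fold higher. Of 25 ATF4 genes 22 rose and none fell by the deposited adjusted p (24 rose when adjusted over the list alone; median 1.17), with CHAC1 10.1-fold (log2 3.34, interval 2.96 to 3.72) and DDIT3 5.54-fold higher. In the authors' deposited table, 14 of 38 constitutive proteasome genes rose (21 when adjusted over the list alone; median 0.41), with PSMC2 at a ratio of 1.99 and PSMD12 at 1.87. PSMB5 had a deposited log2 ratio of 0.22 (interval -0.18 to 0.61). PSMB8 and PSMB9 fell (deposited log2 -0.68 and -0.67, adjusted p 0.019 and 0.045), and PSMB10 had a log2 ratio of -0.82 at an adjusted p of 0.057. The overlapping gene PSMB8-AS1 fell as well (-1.25), so reads shared with it cannot be excluded for PSMB8 and PSMB9. NRF2 targets rose in 10 of 20 cases by the deposited adjusted p (15 when adjusted over the list alone), with HMOX1 at a ratio of 18.4 and OSGIN1 at 14.3. In the endoplasmic reticulum list 9 of 27 rose by the deposited adjusted p (16 when adjusted over the list alone), with HSPA5 at a ratio of 2.55 and SDF2L1 at 1.94.

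Of 20 B-cell precursor genes 10 fell with ONX-0914 at 800 nM in the authors' deposited table (13 when adjusted over the list alone), with VPREB1 at a ratio of 0.233 and CD79B, a B-cell receptor chain, at 0.321. Of 5 T-cell and NK-cell markers 3 fell and 1 rose (3 and 1 when adjusted over the list alone; median log2 -0.52, adjusted p = 0.053), and of 11 myeloid markers 2 fell (4 when adjusted over the list alone; median -0.38, adjusted p = 0.11). Of 25 G2/M genes 12 fell by the deposited adjusted p (19 when adjusted over the list alone), with KIF20A at a ratio of 0.533 and CDC20 at 0.531. Interferon-stimulated genes fell in 6 and rose in 1 of 20 cases (13 and 2 when adjusted over the list alone); OAS3 had a deposited log2 ratio of -0.81 and XAF1 one of 0.80. The largest deposited falls among called genes at 5 CPM or more in either group were those of LCN8 (-2.68), CD248 (-2.59), F2RL3 (-2.33), SLA (-2.30) and LINGO3 (-2.28). The median deposited log2 ratio of all genes was -0.09, and 405 genes were higher and 1141 lower (26.2% higher). After recentring on that median the split was 588 higher and 715 lower (45.1% higher). At an adjusted p of 0.01 the count of changed genes was 523 in place of 1546. With cameraPR at a correlation of 0.05, the calls for interferon (adjusted p = 0.076), immunoproteasome (0.064) and DNA replication (0.37, median -0.22) lists were lost.

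ONX-0914 at 50 nM changed HSPA1A, at 187 CPM against 45.9 CPM in the authors' deposited table (4.07-fold, log2 2.02, interval 1.60 to 2.45, adjusted p = 0.0020). HSPA6 had a deposited log2 ratio of 1.98 at an adjusted p of 0.33, and OSGIN1 one of 1.26 at 0.99. PSMB5, PSMB8, PSMB9 and PSMB10 had deposited log2 ratios of 0.01, -0.07, 0.02 and -0.13, with interval bounds between -0.67 and 0.44. As lists, heat shock (median 0.22), constitutive proteasome (0.14), with PSMC2 at a deposited log2 ratio of 0.51 and an adjusted p of 0.91, and NRF2 genes (0.16) lay above matched random lists, each with an adjusted p of 0.0010. The mitochondrially encoded list had a median of 0.43, also at 0.0010, with MT-ND4L at a deposited log2 ratio of 0.65 and 0 of 13 genes called. Its quartiles were 0.33 and 0.46, so its genes had much the same ratio. This p takes genes as independent and may overstate the support if they move together. The MHC class I list had a median of -0.19 at an adjusted p of 0.0010, with ERAP2 at a deposited log2 ratio of -0.42 and HLA-B at -0.22. Of 10 list calls 5 held with cameraPR at a correlation of 0.05, and those for the ATF4 (median 0.08), endoplasmic reticulum (0.09), DNA replication (-0.11), B-cell (-0.12) and G2/M (-0.10) lists did not, with adjusted p of 0.27, 0.078, 0.15, 0.17 and 0.081.

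**Figure D3:**
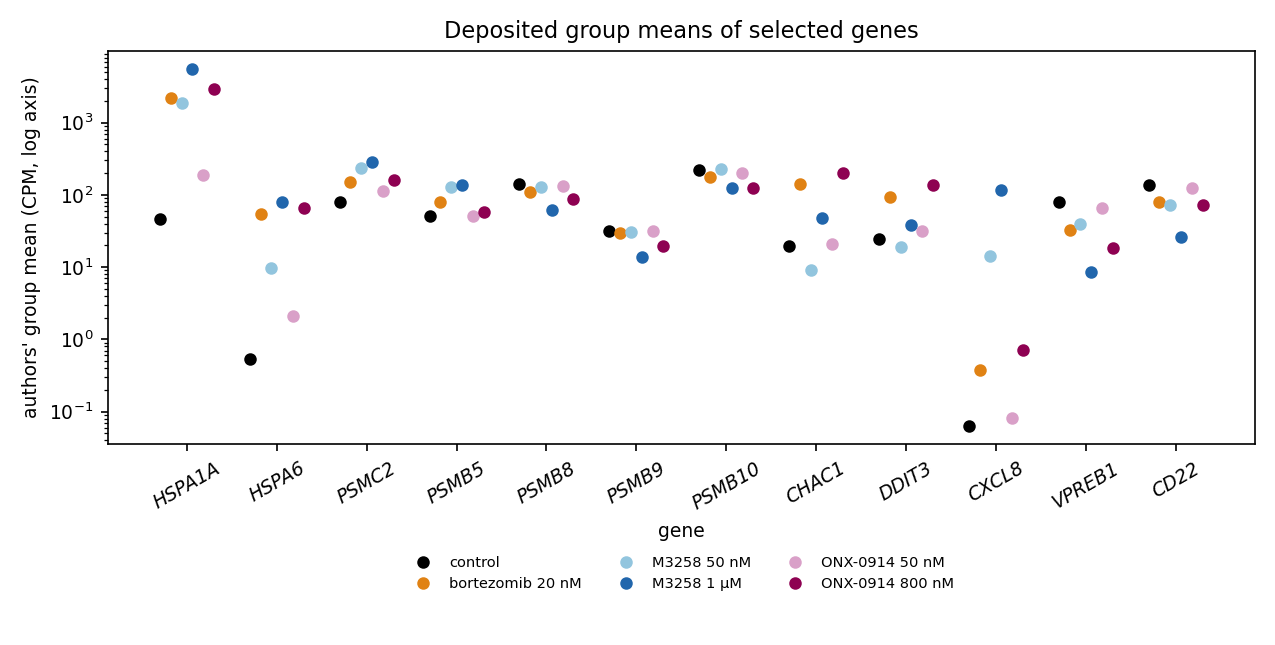
Points give the authors' deposited group means in CPM on a log axis for 12 genes in the 6 groups, with no error bars because the table holds none. HSPA1A stood at 45.9 CPM in control and 5612 CPM with M3258 at 1 µM, and CXCL8 at 0.0622 and 118.7 CPM.

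M3258 and ONX-0914 were compared at the same dose of 50 nM, with the derived standard error. Their potency at this dose is not given here, and ONX-0914 at 50 nM had changed 1 gene against control. At this dose 1051 genes differed, 530 higher and 521 lower with M3258. Of 38 constitutive proteasome genes 33 were higher with M3258 (33 when adjusted over the list alone; median difference 0.98 on the log2 scale), with PSMB5 higher by 1.34 (interval 0.94 to 1.74). Of 28 heat shock genes 25 were higher with M3258 (27 when adjusted over the list alone), with HSPA1A higher by 3.34 (2.92 to 3.77). NRF2 targets were higher in 15 of 20 cases (17 when adjusted over the list alone), with TALDO1 higher by 1.43. PSMB8, PSMB9 and PSMB10 did not differ past the threshold, with differences of -0.05 (-0.40 to 0.31), -0.07 (-0.49 to 0.35) and 0.18 (-0.36 to 0.72). Of 25 ATF4 genes 2 were higher and 3 lower with M3258 (3 and 3 when adjusted over the list alone; median difference 0.04, adjusted p = 0.79), and CHAC1, at -1.20 (-1.58 to -0.82), and DDIT3, at -0.72, were among the lower ones. Of 20 B-cell genes 12 were lower with M3258 (16 when adjusted over the list alone; median difference -0.71). The T-cell and NK-cell marker list was lower too, with 1 of 5 genes called (2 when adjusted over the list alone; median difference -0.51, adjusted p = 0.012). The mitochondrially encoded list differed by a median of -0.69, with 0 of 13 genes called (9 lower when adjusted over the list alone). The largest differences among called genes at 5 CPM or more in either group were those of CXCL8 (7.45), MAP1A (3.71), DYNC1I1 (3.58), VWA5B2 (-3.14), LGR6 (-2.84) and PSD2 (-2.68). Using 6 degrees of freedom in the test alone, 167 genes remained called.

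Between the doses of M3258, 1901 genes differed by the derived test, 566 higher and 1335 lower at 1 µM. Of 25 ATF4 genes 22 were higher at 1 µM (25 when adjusted over the list alone; median difference 1.09), with CHAC1 higher by 2.38 (adjusted p = 2.7e-05). All 5 immunoproteasome genes were lower at 1 µM, with PSMB8 at -1.05 (-1.41 to -0.70) and PSMB10 at -0.89 (-1.43 to -0.35), whereas PSMB5 differed by 0.08 (-0.32 to 0.48). Of 20 B-cell genes 12 were lower at 1 µM (15 lower and 1 higher when adjusted over the list alone), with VPREB3 at -2.70 and VPREB1 at -2.22. The T-cell and NK-cell marker list was lower too (3 of 5 lower and 1 higher; 4 and 1 when adjusted over the list alone; median difference -0.77, adjusted p = 0.012, and 0.053 with cameraPR at a correlation of 0.05). The mitochondrially encoded list had a median difference of -0.58 (adjusted p = 0.00087), with 0 of 13 genes called. KLF5, a transcription factor, and CXCL8 were each higher by 3.06, HSPA6 was higher by 3.05, and SREBF2-AS1 (-2.58) and RASSF4 (-2.45) were lower. Between the doses of ONX-0914 656 genes differed, 195 higher and 461 lower at 800 nM (29.7% higher), against 236 and 260 after recentring (47.6% higher). HSPA6 (4.97), HSPA1A (3.95) and HMOX1 (3.63) were higher at 800 nM, and CD248 (-2.16), LCN8 (-2.05) and DLL1 (-1.85) were lower. With 6 degrees of freedom in the test alone, 258 genes differed between the M3258 doses and 6 between the ONX-0914 doses; with 6 in both the derivation and the test, the latter count was 1324.

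The remaining comparisons set compounds side by side at doses that differ. ONX-0914 at 800 nM and bortezomib at 20 nM differed in 2 genes by the derived test. These were BOLA2 (-2.55), which has near-identical copies, and the ribosomal pseudogene RPL26P30, named after its value was seen. Of 12725 genes 1198 had an unadjusted p under 0.05, a larger share than the 0.05 that unchanged genes would give. As lists, 4 of 26 differed between ONX-0914 and bortezomib. With ONX-0914 the heat shock (median difference 0.23), ATF4 (0.27) and mitochondrially encoded (0.47) lists were higher, each at an adjusted p of 0.0017, and the MHC class I list was lower (-0.31, adjusted p = 0.0026), with 0 members past the threshold over all genes (1 mitochondrial gene higher and 2 MHC class I genes lower when adjusted over the list alone). All 4 calls held with cameraPR at a correlation of 0.05. That correlation was preset, and it may be too low for mitochondrial genes if they move together. CHAC1 differed by 0.49 between them (interval 0.12 to 0.87), HSPA1A by 0.41 (-0.01 to 0.84) and PSMB5 by -0.43 (-0.83 to -0.03), none past the threshold. With 6 degrees of freedom in both the derivation and the test, 70 genes differed. M3258 at 1 µM and bortezomib differed in 3292 genes, 1493 higher and 1799 lower with M3258, and 1601 with 6 degrees of freedom in the test alone. PSMB5 was higher with M3258 by 0.79 (0.39 to 1.18), and 32 of 38 constitutive proteasome genes were higher and 1 lower (32 and 1 when adjusted over the list alone). Of 25 ATF4 genes 12 were higher and 2 lower with M3258 (13 and 4 when adjusted over the list alone; median difference 0.39, adjusted p = 0.0012), a list call lost with cameraPR at a correlation of 0.05 (adjusted p = 0.12). The 2 lower genes were CHAC1 (-1.59) and DDIT3 (-1.28). CXCL8 (8.28), MAP1A (4.04) and DYNC1I1 (3.93) were the largest positive differences, and GP1BB (-4.97), LGR6 (-4.50) and CRIP2 (-3.73) the largest negative ones. M3258 at 1 µM and ONX-0914 at 800 nM differed in 3398 genes, 1932 higher and 1466 lower with M3258 (56.9% higher), against 1477 and 1839 after recentring (44.5% higher), and in 1436 with 6 degrees of freedom in the test alone. CXCL8 was higher by 7.40, CLU, a secreted chaperone, by 4.37 and MAP1A by 4.36 with M3258. GP1BB (-5.40), TMEM276-ZFTRAF1 (-5.01) and LGR6 (-4.25) were lower.

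M3258 at 50 nM was also compared with bortezomib and with ONX-0914 at 800 nM, in comparisons chosen after the data were seen. Against bortezomib 486 genes differed, 300 higher and 186 lower with M3258; 24 of 38 constitutive proteasome genes were higher and 10 of 25 ATF4 genes were lower (34 and 16 when adjusted over the list alone), with CHAC1 at -3.96 (interval -4.34 to -3.58) and SESN2 at -2.57. CXCL8 (5.22), DYNC1I1 (3.47) and PIR (3.03) were higher. Against ONX-0914 at 800 nM 1596 genes differed, 1137 higher and 459 lower (71.2% higher), against 764 and 672 after recentring (53.2% higher). Of 25 ATF4 genes 18 were lower (20 when adjusted over the list alone), with CHAC1 at -4.45 and SESN2 at -3.18. TUBA1B-AS1 (-4.98) was lower too, and CXCL8 (4.34), RN7SL2 (3.36) and MAP1A (3.26) were higher. With 6 degrees of freedom in the test alone, 14 and 99 genes differed in these comparisons; with 6 in both steps, 929 differed against bortezomib.

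**Figure D4:**
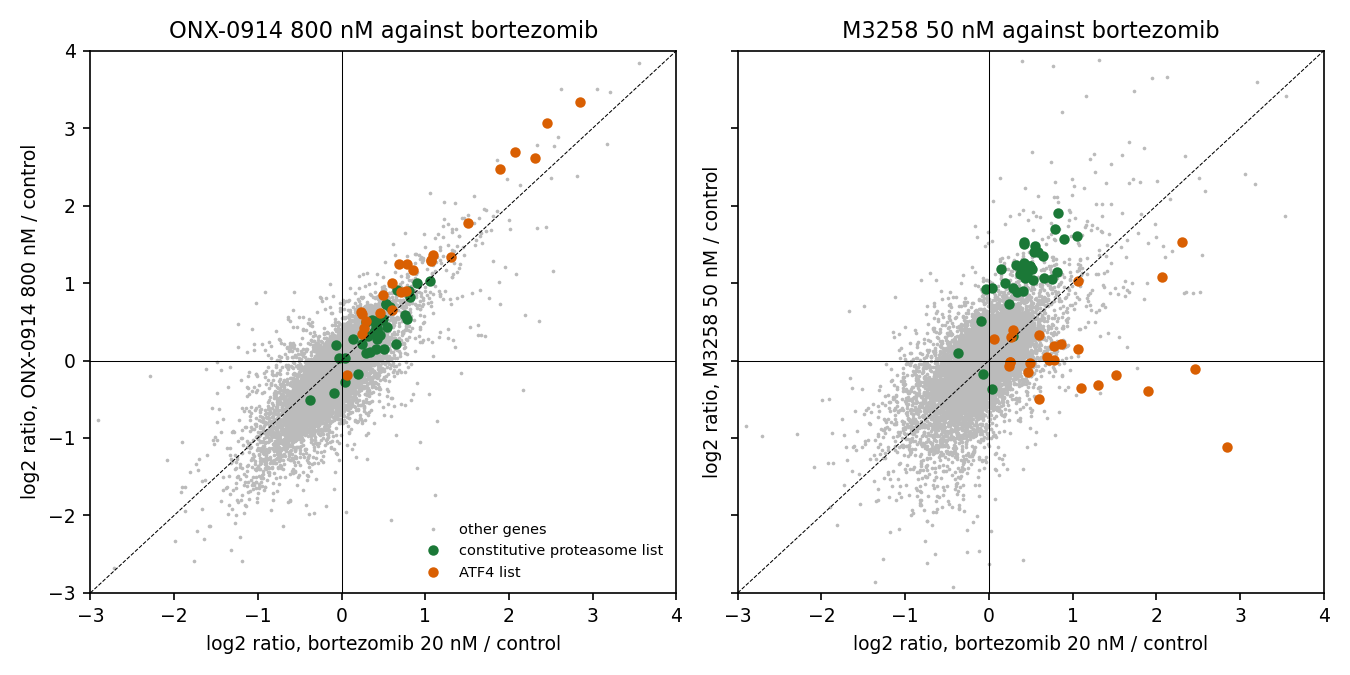
Each point is a gene, with its log2 ratio to control for bortezomib on the x axis and for ONX-0914 at 800 nM (left) or M3258 at 50 nM (right) on the y axis; the dashed line marks equal ratios, and 6 and 8 genes lie outside the plots. The ATF4 list (orange) had medians of 0.77 with bortezomib, 1.17 with ONX-0914 and 0.003 with M3258, and the constitutive proteasome list (green) had 0.42, 0.41 and 1.12.

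Across genes, which are not independent replicates, the deposited log2 ratios of bortezomib and ONX-0914 at 800 nM had a Pearson correlation of 0.79 and a Spearman correlation of 0.75. Unchanged groups against shared controls gave a simulated correlation of 0.50, and the observed covariance was 0.154 against a simulated 0.0293. They shared 145 higher and 207 lower calls, where independent lists would share 5.12 and 21.6. The correlation was 0.65 between bortezomib and M3258 at 50 nM (covariance 0.132 against 0.0293), 0.83 between the doses of M3258 (0.363 against 0.0292) and 0.33 between M3258 and ONX-0914 at 50 nM (0.0376 against 0.0292). Over genes called in either comparison of a pair, these 4 correlations were 0.90, 0.73, 0.89 and 0.66. Picking genes by calls against the shared controls can raise a correlation, and no simulated value was computed for such genes. For M3258 and ONX-0914 at 50 nM these were 1202 genes, and ONX-0914 had 1 call. The 2 control libraries cannot be split, so the part of any excess that comes from them is not known. These were 4 of 10 pairs computed.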

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

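All tests in this part were chosen after the results were seen, except the length test of the 4 lists together, whose bounds were written before it was run on lists picked for being lower.

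In all, 17 genes were called in opposite directions by 2 treatments, so the derived test of the difference passes nearly by construction and adds no support. CHAC1 had the largest, with M3258 at 50 nM minus ONX-0914 at 800 nM at -4.45 on the log2 scale. For that same pair, ANKRD18DP differed by -1.93, RGS16 by -1.74, GATA3 by -1.63, XAF1 by -1.49, MAP2K3 by 1.47 and LINC00963 by 1.05. For M3258 at 1 µM minus ONX-0914 at 800 nM, the differences were 1.86 for TUBB2A, 1.79 for KLF10, 1.77 for SLFN5, 1.73 for MIR23AHG, 1.68 for VAMP2, 1.61 for PLEKHO2, 1.38 for PNRC1 and -0.90 for TMEM97. UNC5B differed by 1.40 between M3258 at 1 µM and 50 nM, and HNRNPA1L2, which resembles other genes of its family, by 1.11 between bortezomib and M3258 at 1 µM. Groups of 2 libraries are too small to look for outlying libraries.

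The ATF4 list was lower with M3258 at 50 nM than with bortezomib. Scaling of the group means is argued against, since the median difference of the list was -0.69 after recentring. A smaller response to M3258 at 50 nM in every stress list is argued against by a median difference of 0.70 in the proteasome list and 0.38 in the NRF2 list; the heat shock list differed by 0.05 (adjusted p = 0.54) and the endoplasmic reticulum list was lower (-0.12, adjusted p = 0.038). The ATF4 median of 1.07 at 1 µM argues against a lack of ATF4 response to M3258 at any dose. That value is against control, and cannot exclude an ATF4 response to M3258 that is weak beside its other responses. Against bortezomib, M3258 at 1 µM had 12 ATF4 genes higher and 2 lower (median difference 0.39), and a proteasome median difference of 0.81. It also stays open that the doses of the 2 compounds were not matched in potency and that the treatment time is not given. These points were not tested.

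The ribosomal, mitochondrial, histone and metallothionein lists, 58 genes with a median transcript length of 720 bases against 996 for all genes, were lower with M3258 at 1 µM (median log2 -0.56; 34 fell, 0 rose). Transcript length is argued against as the whole cause, since random lists matched on length had a median log2 ratio of -0.064, against -0.56. The joint median lay at percentile 0 of 10000 such lists. The mitochondrial, histone and metallothionein lists alone lay at 0.2, 0.03 and 0. These percentiles take genes as independent and were computed on lists picked for being lower, so they may overstate the support. For the ribosomal list alone it was 0.91, above the bound of 0.5, so for that list length and treatment cannot be told apart. A few genes taking most of the counts is argued against, since the 10 highest genes held 7.37% with M3258 at 1 µM and 7.31% in control. These shares differed by 0.061 percentage points. The 10 genes were taken for each group and need not be the same, so rises and falls among them could cancel and were not examined. At 50 nM all 4 lists were lower too, with medians of -0.19, -0.27, -0.78 and -1.32 in the order above. Adjusted p against random lists matched on expression was 0.0095, 0.017, 0.0042 and 0.00074. The ribosomal and mitochondrial calls were lost with cameraPR at a correlation of 0.05. The joint median at 50 nM was -0.22, at percentile 0.01 of lists matched on length. It lay at percentile 2.63 with bortezomib, 86.3 with ONX-0914 at 800 nM and 92.7 with ONX-0914 at 50 nM. The dose of M3258 stays open. The difference between 1 µM and 50 nM lay at percentile 0, but it reuses the value by which the lists were picked. RNA quality per library could not be examined, so a technical origin may remain.

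Of 5 immunoproteasome genes 4 fell with M3258 at 1 µM, while 33 of 38 genes of the constitutive proteasome list rose. Most of that list is not particular to the constitutive form, so these counts do not set one form against the other. Reads of the antisense gene PSMB8-AS1 on chromosome 6 are argued against for PSMB10 and PSME1 by their location on chromosomes 16 and 14; of the 3 genes outside that locus 2 had intervals below 0, and that of PSME2 reached 0.13. PSMB8-AS1 ends at 32846495 and PSMB9 at 32859585, so PSMB8-AS1 overlaps only a part of PSMB8 and of PSMB9. Within its overlap with PSMB8, reads cannot be told apart because the libraries do not mark strand. Within its overlap with PSMB9, both genes lie on the plus strand, so shared stretches cannot be told apart either. How many reads fall in these overlaps was not examined. PSMB8-AS1 went from 61.1 CPM in control, 78.1% of the fall of PSMB8, to 13.2 CPM, and its own fall came to 61.3% of that of PSMB8. PSMB8-AS1 also fell with M3258 at 50 nM (log2 -0.82), bortezomib (-0.97) and ONX-0914 at 800 nM (-1.25). PSMB8 had log2 ratios of -0.12, -0.34 and -0.68 in these treatments, which does not settle the share of its reads. The dose of M3258 stays open: 5 of the 5 genes were lower at 1 µM than at 50 nM, but that difference reuses the 1 µM values in which the pattern was seen.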

How the results depend on the processing

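The thresholds of 0.01 and of 1 on the log2 scale were chosen before the data were examined; the 5 CPM floor, recentring, standard errors from other comparisons, 6 degrees of freedom, length matching and cameraPR were chosen after seeing the data. Other normalizations, the DESeq2 test, no filter, another pseudocount, 2-group fits, leaving out each replicate, fry and an estimated correlation had also been chosen before and were not run, because they need values per library. No paired analysis was possible because the table holds no values per library. The depth reached by each library is unknown, and what the stated 20 M reads per library would limit was not assessed.

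Stricter thresholds lowered counts by construction. At an adjusted p of 0.01 the counts for bortezomib, M3258 1 µM, M3258 50 nM and ONX-0914 800 nM against control were 123, 3369, 541 and 523, and at a log2 change of 1 or more 160, 2226, 484 and 456. At 0.01, the differences M3258 1 µM minus 50 nM, ONX-0914 800 minus 50 nM, M3258 minus ONX-0914 at 50 nM, M3258 1 µM minus bortezomib, ONX-0914 800 nM minus bortezomib, M3258 1 µM minus ONX-0914 800 nM, M3258 50 nM minus bortezomib and M3258 50 nM minus ONX-0914 800 nM gave 612, 151, 391, 1583, 0, 1481, 158 and 507. At a log2 change of 1 or more they gave 587, 227, 375, 1147, 2, 1115, 185 and 392.

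The differences between treatments depend strongly on the degrees of freedom. With 6 in the test only, the residual number of 12 libraries in 6 groups, the same 8 differences gave 258, 6, 167, 1601, 0, 1436, 14 and 99 genes. That form was tried before the other, in which 6 is used to derive the standard error as well; the latter was added because the former had removed most calls, and gave 2564, 1324, 1547, 3570, 70, 3664, 929 and 1858. The test-only form also departs from the deposited calls it should return: bortezomib against control would have 7 genes in place of 402. Over all genes and all 5 comparisons, a measure other than the pairwise difference used to choose the degrees of freedom, the relative residual of the fitted standard error had a median of 7.16% at 6 and 2.52% at 12.75 degrees of freedom. The true number is not given in the sources used here, so counts of differences between treatments are less certain than those against control.

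With a 5 CPM floor, ONX-0914 800 nM against bortezomib gave 1 gene in place of 2, because RPL26P30 was not tested; the other 12 counts stayed within 1.5 times. For ONX-0914 at 50 nM, cameraPR at a correlation of 0.05 called 6 lists in place of 10; the cause was not tested. Recentring left the total of each comparison within 1.5 times, but the lower calls of ONX-0914 at 800 nM went from 1141 to 715 against control and from 461 to 260 against 50 nM, by construction of the shift. Over genes called in either comparison, 5 of 10 correlations between comparisons moved, each upward, which the picking of genes by their calls can cause. Recentring was the only alternative in which a change of direction could have been recorded, and no named gene or called list changed direction in it. Among results for named genes, 14 lost their call at an adjusted p of 0.01 and 3 on recentring.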

Other observations

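The lists in this part were fixed before the data were examined; the test against random lists was run for all of them, and the genes named here were picked after their values were seen. MLL-AF4 target genes, the genes bound by the fusion protein, went both ways with M3258 at 1 µM: by the authors' deposited table, 8 of 25 rose, among them RUNX1, CDK6 and PROM1, and 5 fell, among them LMO2 and CSPG4 (8 and 5 when adjusted over the list alone; median log2 -0.04, adjusted p = 0.80 against random lists). At 50 nM 0 rose and 3 fell by the deposited adjusted p (median -0.18, adjusted p = 0.013). With M3258 at 1 µM 7 of 18 pro-apoptotic genes rose and 5 fell, and 3 of 8 anti-apoptotic genes rose and 1 fell by the deposited adjusted p; neither list passed against random lists (adjusted p = 0.094 and 0.28). p53 targets rose in 8 and fell in 4 of 23 cases with M3258 at 1 µM by the authors' deposited table (adjusted p = 0.80 against random lists). Of all genes, 43.6% were called in that comparison.

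Of 11 myeloid markers 1 rose and 5 fell at 1 µM by the authors' deposited table (adjusted p = 0.28 against random lists). With 1 µM, 3 cholesterol synthesis genes rose and 9 fell of 22 (adjusted p = 0.046, a call lost with cameraPR). MYC and ribosome biogenesis genes rose in 4 and fell in 7 of 23 cases by the deposited adjusted p. DNA replication genes rose in 2 and fell in 7 of 27. Neither of these lists passed against random lists (adjusted p = 0.85 and 0.28). MHC class I genes rose in 2 and fell in 3 of 12 cases with M3258 at 1 µM (adjusted p = 0.88 against random lists). With ONX-0914 at 800 nM 0 rose and 2 fell, and the list was lower than random lists (median -0.33, adjusted p = 0.021).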
